A study of Mus musculus with 8 samples.

How the data were processed

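Total RNA of mouse embryonic stem cells was made into standard Illumina libraries from cells moved into lysis solution, per the labels' protocols. The deposited values are labelled FPKM per gene and library in the file headers. FPKM stands for fragments per kilobase, scaled to a total per library, and the headers do not say which total. The submitters' processing notes name CASAVA 1.4, HISAT2 and the mm10 genome build. The program that counted reads, the annotation, the FPKM formula and any use of strand are not given in the sources used here, so reads from overlapping or antisense genes could not be told apart. The table held 58420 gene rows, of which 6082 had no value in any library and 52338 had values. Of the latter, 52081 matched a GENCODE M21 gene (GRCm38, the assembly that mm10 names) by Ensembl identifier and 257 did not. Symbols, coordinates and exon lengths come from that match.

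Depth was recovered from the values. The deposited FPKM times the union exon length was a whole multiple of what 1 read is worth, within a tolerance of 0.02, for 98.3% to 98.9% of values under 100 reads per library. This gave read counts and totals per library, which were used for depth, floors and read ratios, and as input to 1 added alternative. The totals lay near the sum over matched genes, with 6415150 against 6407763 in control replicate 1 and 3658356 against 3407462 in control replicate 2. They are therefore taken as reads assigned to genes, and the number of all mapped or sequenced reads is unknown. Floors of 3 reads and exact 95% intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

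Samples were grouped by the labels into control, sh, sd and dd, with 2 libraries each. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with genes kept at a mean FPKM of at least 1 over the 8 libraries (14561 genes). All 4 groups were fitted together without covariates (4 residual degrees of freedom), eBayes used a mean-variance trend, and p-values were two-sided with Benjamini-Hochberg adjustment per contrast at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The 6 pairwise contrasts, an F test over the 3 contrasts against control, and 29 gene lists fixed before the data were examined were tested. Lists with at least 5 members above the filter (27 of 29) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry, a test of whether a list's genes move one way on balance, were alternatives. Camera with an estimated correlation also tests on the residual degrees of freedom of the fit, 4 here and 3 with the block. The preset form uses the number of genes instead. A call lost with an estimated correlation may therefore reflect the few libraries rather than correlated genes.

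Most genes named in the text were chosen by a rule fixed before the data were examined. Actb, Gapdh, the olfactory receptor class, the genes called with voom, the Pou5f1 copy and the genes under the other observations lie outside it and were chosen after their values were seen. The rule takes the called genes with the largest change in each contrast, and in a contrast with fewer than 5 of them it takes the 5 higher and 5 lower genes with the smallest unadjusted p and separate libraries, leaving out predicted, clone and pseudogene symbols, and gives them as values. It also takes up to 4 members of each list with the smallest unadjusted p per contrast against control, of which examples are printed, and Pou5f1, Sox2 and Nanog in every group. The lists were general and naive pluripotency, formative and primed, neuroectoderm, mesoderm and streak, primitive endoderm, trophoblast, 2-cell-like, fibroblast feeder, interferon response, p53 targets, cell cycle, LIF and Stat3, FGF and ERK feedback, Wnt targets, Nodal and BMP targets, glycolysis and hypoxia, cholesterol synthesis, Atf4 stress, endoplasmic reticulum chaperones, Hox, germline, imprinted, chromatin repressors, apoptosis signalling, extracellular matrix and adhesion, cytosolic ribosomal proteins, mitochondrial genome and replication histones.

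Alternatives set before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 FPKM, quantile and median ratio scaling, a fit of only the groups compared, robust variance moderation, a minimum absolute log2 change of 1, the replicate number as a block (3 residual degrees of freedom), and leaving out each library in turn. Alternatives added after seeing the data were voom weights on recovered reads, with and without the block, protein-coding genes only with the block, an estimated correlation with the block, and the block without each replicate 2 library. Leaving out 1 library without the block sets unequal replicate numbers against each other, so any difference between the numbers enters the contrast. With all replicate 2 libraries left out, each group has 1 library and no residual degrees of freedom, so no test was made. Sequence shared between genes was measured as the share of sampled 31-base stretches of a gene's longest transcript that occur in transcripts of another gene. The fits were tested on simulated data for sh against control: the fit with the block gave 7 false calls, and a cell cycle list raised by 0.6 log2 was called in both fits. Simulated noise was independent between genes, so the list result does not cover lists whose genes vary together. Shared controls were simulated 100 times with unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The level of linc1393 was not analysed here.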

Results

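RNA abundance was measured by sequencing in mouse embryonic stem cells (mESCs), pluripotent cells derived from the early embryo. The series concerns linc1393, a long intergenic non-coding RNA, and its part in maintaining pluripotency. There were 8 libraries in 4 groups of 2: untreated wild-type cells (control) and cells treated with reagents that the labels call sh-, sd- and dd-linc1393 (sh, sd and dd). The labels do not say what sd and dd stand for, and the names are used here as given. No gene identifier in the table was tied to linc1393, so its level was not analysed here and the treatments could not be checked on their target. The controls were untreated, so a difference from control cannot be assigned to linc1393 rather than to giving a reagent. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

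The libraries differed in depth, here the reads assigned to genes, recovered from the steps between low FPKM values as described under the processing. Control replicate 1 held 6415150 reads and control replicate 2 held 3658356, the lowest of the 8. The sh libraries held 13738596 and 13972289 reads, the sd libraries 20346875 and 15365326, and the dd libraries 19161674 and 20386654. At 3 reads, the limit that a count of 0 allows, a transcript of 1 kb would have 0.82 FPKM in control replicate 2 and 0.147 FPKM in dd replicate 2, counting error only.

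The 8 libraries separated by replicate number before they separated by group. Spearman correlations across the 14561 genes tested were 0.77 to 0.951 between libraries with the same number and 0.421 to 0.731 between the libraries of a group (genes are not independent replicates). The first principal component held 78.4% of the variance and placed all replicate 1 libraries apart from all replicate 2 libraries. Actb, which encodes cytoplasmic beta-actin (chromosome 5, 142903115 to 142906754), had 9006 to 15910 FPKM in the 4 replicate 1 libraries and 55.3 to 76.6 FPKM in the 4 replicate 2 libraries. Gapdh, a glycolytic enzyme gene on chromosome 6, went the other way, with 4.07 to 10.1 FPKM against 37.4 to 74.9 FPKM. Of 1135 olfactory receptor genes, which belong to the nasal epithelium, 5.29% to 8.19% had a value above 0 in replicate 1 libraries. In replicate 2 libraries the share was 86.4% in control, 97.8% in sh, 96.5% in sd and 50.4% in dd. Actb, Gapdh and the olfactory receptors were chosen after their values were seen. Because of this split, differences within each replicate number and a fit with the replicate number as a block are given beside the results.

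**Figure D1:**
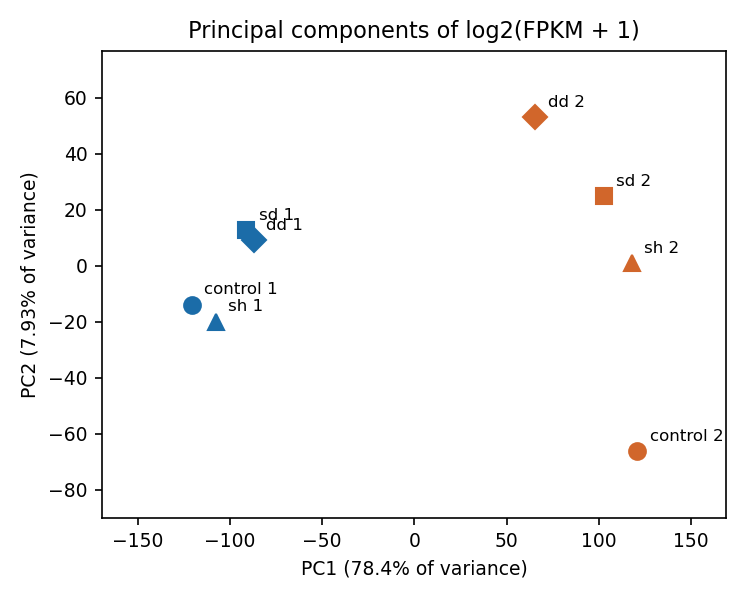
Principal components of log2(FPKM + 1) over 14561 genes, with the share of variance on each axis. Each point is a library, coloured by replicate number and shaped by group; the horizontal axis, with 78.4% of the variance, separates replicate 1 from replicate 2 in all 4 groups.

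**Figure D2:**
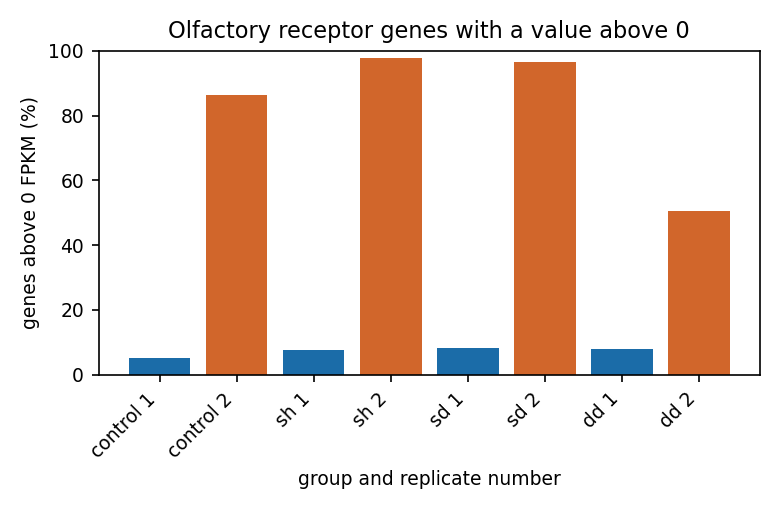
Share of 1135 olfactory receptor genes with a value above 0 FPKM, in percent, per library. Bars are single libraries; replicate 1 libraries lie at 5.29% to 8.19% and replicate 2 libraries at 50.4% to 97.8%.

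Of the core pluripotency factors, Pou5f1 (Oct4) had lower values in each treated library than in the control library of the same number, while Nanog stayed within a narrow range. Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772, GRCm38) had a mean of 167 FPKM in control (SD 119, n = 2), with 83.1 and 251 FPKM in the libraries. The mean was 19.4 FPKM in sh (SD 6.66, n = 2), 73.8 FPKM in sd (SD 79.2, n = 2) and 37.1 FPKM in dd (SD 22.7, n = 2). In sd the libraries held 17.8 and 130 FPKM, so sd overlapped the control range. Of its sampled 31-base stretches, 11.2% occurred in another gene's transcripts, and an annotated gene, Gm19553, overlaps it on the other strand. Nanog (ENSMUSG00000012396, chromosome 6, 122707489 to 122714633), which shares 11% of its stretches, had 229 FPKM in control (SD 19.7, n = 2), 238 in sh (SD 11.8, n = 2), 302 in sd (SD 46.7, n = 2) and 280 in dd (SD 7.83, n = 2). Sox2 (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461) had 245 FPKM in control (SD 64.6, n = 2), 219 in sd (SD 16.8, n = 2) and 303 in dd (SD 96.3, n = 2). In sh, Sox2 had 177 FPKM in replicate 1 and 19.7 FPKM in replicate 2, and without sh replicate 2 its log2 difference from control was -0.44. Sox2 lies inside the non-coding gene Sox2ot on the same strand.

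None of these differences passed the test over all genes. The log2 difference of Pou5f1 from control was -2.87 in sh (SE 1.12), -1.55 in sd (SE 1.12) and -2.08 in dd (SE 1.12) on the log2(FPKM + 1) scale, each with a limma adjusted p of 1. With the replicate number as a block, the limma adjusted p was 0.999, 0.723 and 0.553 in that order. Adjusted over the 25 genes of the general pluripotency list alone, Pou5f1 was called in sh with the block and not without it. It was not called in sd or dd in this way. Within replicate 1 the difference was -1.74, -2.16 and -1.93, and within replicate 2 it was -4.00, -0.95 and -2.22. Over all alternatives the difference ranged from -3.66 to -2.08 in sh, from -2.95 to -0.15 in sd and from -2.87 to -1.28 in dd. The value of -0.15 was without sd replicate 1, that of -2.95 without sd replicate 2, and that of -1.28 without control replicate 2. Those fits had no block, so the split between replicate numbers enters them.

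**Figure D3:**
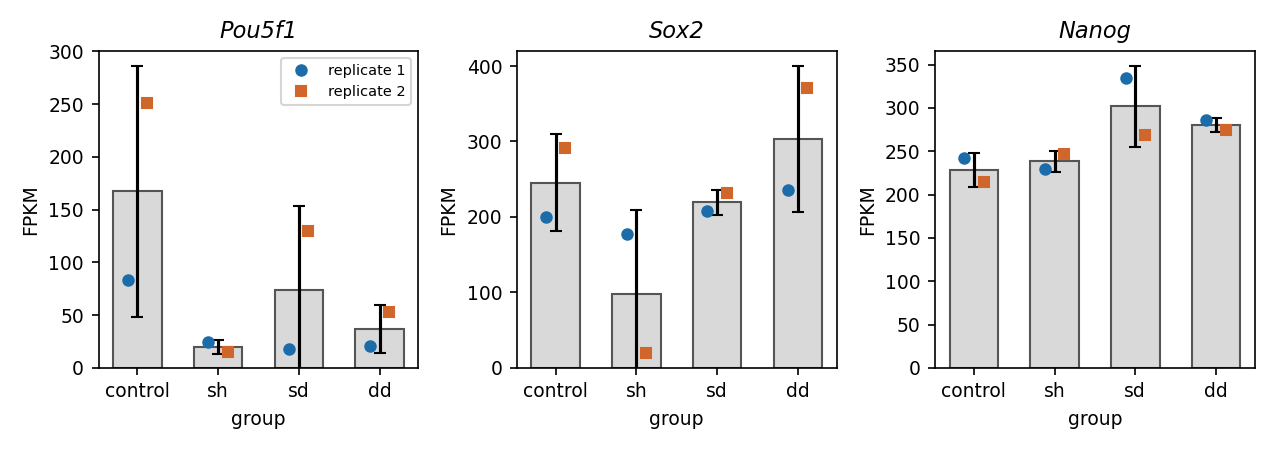
FPKM of Pou5f1, Sox2 and Nanog in the 4 groups. Bars are group means, error bars 1 SD (n = 2), drawn no lower than 0, and points the libraries by replicate number; Pou5f1 has 167 FPKM in control and 19.4 to 73.8 FPKM in the treated groups.

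The comparison of sh with control asked which transcripts differed after the sh-linc1393 treatment. Genes of the cell cycle list were higher in sh as a group: 27 of 29 members had a positive difference and their median was 0.46 log2, against 0.15 for all genes tested (0.04 after quantile normalization and -0.01 after median ratio scaling). Its camera adjusted p was 0.0128, and the adjusted p was 0.79 with an estimated correlation. The extracellular matrix and adhesion list was also higher, with all 19 members positive and a median of 0.42 log2 (camera adjusted p = 0.0323; adjusted p = 0.973 with an estimated correlation). The transcripts of the mitochondrial genome were lower, with 14 of 15 members negative and a median of -0.31 log2 (camera adjusted p = 0.0403; 0.973 with an estimated correlation). Genes of the replication histone list were lower at a median of -0.38 log2, with 11 of 16 members negative (camera adjusted p = 0.0461, and 0.973 with an estimated correlation). That list also holds H1f0, which is not replication-dependent and was higher in sh, at 0.282 to 0.93 log2 over the alternatives. All 4 calls were thus lost with an estimated correlation. That form has only 4 residual degrees of freedom, so few calls could hold in it whatever the correlation. The estimated correlation was 0.0148 for the cell cycle, 0.0761 for the matrix, 0.0988 for the mitochondrial and 0.481 for the histone list, against the preset 0.01.

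Among the cell cycle genes, Bub1b, a spindle checkpoint kinase, had 11.2 FPKM in control (SD 1.78, n = 2) and 21.3 in sh (SD 9.33, n = 2). Mcm4, a subunit of the replicative helicase, had 50.2 FPKM in control (SD 29.9, n = 2) and 84.3 in sh (SD 38.9, n = 2). Of the matrix genes, Lamb1, a laminin chain, had 2.94 FPKM in control (SD 1.89, n = 2) and 4.94 in sh (SD 0.234, n = 2). Of the mitochondrial transcripts, mt-Co1, a cytochrome c oxidase subunit, had 7087 FPKM in control (SD 2107, n = 2) and 4486 in sh (SD 3167, n = 2); 65.1% of its sampled 31-base stretches occur in another gene's transcripts, so its reads are uncertain. The 4 lists differed in how the replicate numbers behaved. Within replicate 1 and replicate 2 the cell cycle median was 0.19 and 0.63, the matrix median 0.29 and 0.67, the mitochondrial median -0.01 and -0.61, and the histone median 0.50 and -1.17. With the block, the 4 lists were called by camera (adjusted p = 7.87e-04, 0.00726, 5.53e-06 and 0.00867), and none was with the block and an estimated correlation (adjusted p = 0.932 for each). The blocked calls were also lost without control replicate 2 (adjusted p = 0.476 for each) and without sh replicate 2 (adjusted p = 0.336, 0.424, 0.336 and 0.876). Without a block and without control replicate 2, none of the 4 was called. The medians there were 0.336 for the cell cycle, 0.51 for the matrix, -0.689 for the mitochondrial and 1.07 for the histone list. Without sh replicate 1 only the mitochondrial call held (histone median 0.09), and without sh replicate 2 only the cell cycle call (mitochondrial median -0.03). Without control replicate 1 the mitochondrial call was lost (median -0.397). Such unblocked fits set unequal replicate numbers against each other, so the split between the numbers enters them. Median ratio scaling ended all 4 calls (adjusted p = 0.107 to 0.131), and quantile normalization ended the matrix and mitochondrial calls (adjusted p = 0.0798 and 0.721). Without a filter on low values none of the 4 was called (adjusted p = 0.053 to 0.569). The histone call was also lost with a pseudocount of 0.1 (median 0.02, adjusted p = 0.479) or 0.5 (adjusted p = 0.168), with a mean of at least 5 FPKM (median 0.12, adjusted p = 0.829), and with voom (adjusted p = 0.46, and 0.0912 with the block).

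No single gene was called between sh and control by limma among 14561 genes. At an unadjusted p under 0.05 there were 32 genes, against 728 by chance, and 480 with the block, which also called 0. The voom weights on recovered reads called 0 genes without the block (6 unadjusted) and 0 with it (358 unadjusted). On simulated data for this comparison, the fit without a block recovered 0% of 50 genes changed 16-fold, and the fit with it recovered 98% of 50 genes changed 8-fold and 64% of 50 changed 4-fold. The count of 0 without a block therefore says little about changes up to 16-fold. The simulated noise was normal, equal in all libraries and taken from the spread of the blocked fit, and genes of low level were not changed. The real libraries may vary more, so the count of 0 with the block does not exclude 8-fold changes either.

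The genes with the smallest unadjusted p and separate libraries are given as values. Magea4, a melanoma antigen family member (chromosome X, 72222017 to 72222964), had 0 and 1 reads in the control libraries and 77 and 68 in sh. The ratio of reads was 52.7, with an exact 95% interval of 9.31 to 2100 (counting error only). Chac2, a glutathione-degrading enzyme (chromosome 11, 30976707 to 30986350), had 1.37 FPKM in control (SD 1.60, n = 2) and 15.4 in sh (SD 11.8, n = 2), and overlaps Asb3 on the other strand. Inafm2 had 0.627 and 4.26 FPKM, the non-coding Platr4 0.336 and 2.49, and Catsperz 0.510 and 3.09 in control and sh. Catsperz shares 48.1% of its sampled 31-base stretches with another gene and overlaps Kcnk4 on the same strand, so its reads are uncertain. On the lower side, the interferon-inducible Ifi27l2a (chromosome 12, 103442167 to 103443680) had 6.36 FPKM in control (SD 4.82, n = 2) and 0.386 in sh (SD 0.547, n = 2). Npy, which encodes neuropeptide Y, had 3.21 and 0.379 FPKM, Smpdl3a 4.30 and 0.399, and the POU factor gene Pou3f1 2.65 and 0.457. Their log2 differences from control lay between -2.29 and -1.34, each with a limma adjusted p of 1.

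The comparison of sd with control gave the replication histone list as the called list, with a median of -0.61 log2 and 12 of 16 members negative (camera adjusted p = 0.0155). The adjusted p was 0.901 with an estimated correlation. Within replicate 1 the median was 0.02 and within replicate 2 it was -1.41, and without control replicate 2 it turned to 0.74. The call was also lost without sd replicate 1 (median -0.12), with median ratio scaling (adjusted p = 0.0593), with a pseudocount of 0.1 (adjusted p = 0.0567), without a filter (adjusted p = 0.0873) and with a mean of at least 5 FPKM, where the median was 0.24. With the block it was called (adjusted p = 0.0085), but not with an estimated correlation as well (adjusted p = 0.948). Members such as Hist1h4a had 0 FPKM in control replicate 1 and 19.3 in control replicate 2, and 0 and 2.54 FPKM in the sd libraries. Hist1h4h had 0 and 18.6 FPKM in control and 0 and 2.63 in sd. These genes share 49% and 50% of their sampled stretches with other genes. The genes of the naive pluripotency list had a median of 0.45 log2 with 21 of 23 members positive, against 0.17 for all genes. That list was not called without a block (camera adjusted p = 0.159) and was called with it (adjusted p = 0.0162), but not with the block and an estimated correlation (adjusted p = 0.935). Within the replicate numbers its medians were 0.53 and 0.47. The cell cycle list, with 27 of 29 members positive and a median of 0.44, had a camera adjusted p of 0.0572, and 0.0162 with the block. With the block and an estimated correlation its adjusted p was 0.948. Without a block, both were called by camera without a filter on low values (adjusted p = 0.0464 and 0.0266), and the cell cycle list with voom (adjusted p = 0.0357). Without control replicate 1 the naive and cell cycle medians were 0.525 and 0.461, and without sd replicate 2 the cell cycle median was 0.576. Those unblocked fits set unequal replicate numbers against each other, so the split between the numbers enters them. With an estimated correlation the adjusted p of both lists without a block was 0.785. With the block, none of the naive, cell cycle and histone lists was called without control replicate 2 or without sd replicate 2, and the histone median without control replicate 2 was 0.239.

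Of the naive genes, Nr5a2, an orphan nuclear receptor gene (chromosome 1, 136842571 to 136960448), had 7.19 FPKM in control (SD 2.05, n = 2) and 19.6 in sd (SD 16.0, n = 2). Tfcp2l1, a transcription factor of naive pluripotency, had 7.95 FPKM in control (SD 0.640, n = 2) and 11.8 in sd (SD 0.889, n = 2). Tdh, threonine dehydrogenase, had 48.8 FPKM in control (SD 5.16, n = 2) and 75.7 in sd (SD 15.2, n = 2), and shares 25.3% of its sampled stretches. No gene was called by limma between sd and control. There were 50 genes at an unadjusted p under 0.05, and 945 with the block, which called 0. By chance 728 would be expected, and 727 with voom. Genes are not independent, so a count above that is not a call. With voom the counts were 0 called without the block (9 unadjusted) and 0 with it (707 unadjusted).

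Of the genes named by rule, 2 microRNA genes were at 0 in control. Mir6400 (chromosome 4, 15942900 to 15942991) had 13 and 9 reads in the sd libraries and 0 in the other 6 libraries. It lies within Decr1 on the same strand, and its mean of 6.66 FPKM lies below what 3 reads per library would give in control, so no fold is given. Mir3473b had 4 and 3 reads in sd and 0 in control, which is too few for a fold. Magea4 had 70 and 47 reads in sd (ratio of reads to control 33, exact 95% interval 5.81 to 1310). Defa30, a defensin gene, had 44 and 13 reads in sd and 0 and 1 in control (ratio 16.1, interval 2.77 to 646). Most of its sd reads came from sd replicate 1, so the ratio depends on that library. Of its sampled stretches, 67.6% are shared with other genes. Chac2 had 9.73 FPKM in sd (SD 5.79, n = 2). On the lower side, Ifi27l2a had 29 and 5 reads in the control libraries (9.76 and 2.95 FPKM) and 0 and 3 in sd (0 and 0.422 FPKM). Control replicate 1 held most of these reads, so no pooled ratio is given. Npy had 0.404 FPKM in sd, and C1qtnf12 had 3.87 in control and 1.06 in sd. Mir1983 had 7.83 and 1.61 FPKM, and Snord8, a small nucleolar RNA gene, had 8 reads in control and 0 in sd and lies within Chd8.

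In the comparison of dd with control, the cell cycle list was higher, with 24 of 29 members positive and a median of 0.46 log2 against 0.06 for all genes (camera adjusted p = 0.0312; 0.936 with an estimated correlation). Its medians were 0.37 within replicate 1 and 0.39 within replicate 2. Genes of the replication histone list were lower, with 14 of 16 members negative and a median of -0.75 log2 (camera adjusted p = 0.0312, and 0.936 with an estimated correlation). Their medians within the numbers were 0.30 and -1.28, and without control replicate 2 the median turned to 0.84. Both calls were also lost without dd replicate 1 (adjusted p = 0.51 and 0.0743) and with median ratio scaling (adjusted p = 0.0942 and 0.0718). The cell cycle call was also lost without control replicate 2 (median 0.23, adjusted p = 0.924) and with quantile normalization (adjusted p = 0.0995). A pseudocount of 0.1 ended both calls (adjusted p = 0.123 and 0.182), as did a mean of at least 5 FPKM (adjusted p = 0.343 for each). The histone call was lost without a filter (adjusted p = 0.162) and with voom (adjusted p = 0.144, and 0.0919 with the block). With the block, 2 more lists were called: the naive pluripotency list, at a median of 0.39 (adjusted p = 0.0474; 0.245 without the block), and the mitochondrial genome, at a median of 0.37 (adjusted p = 0.0319; 0.514 without the block). With an estimated correlation the adjusted p of both was 0.936, and with the block as well none of the 4 lists was called (adjusted p = 0.888 for each). The blocked calls depended on single libraries, and none of the 4 held without dd replicate 2 (adjusted p = 0.141 for the cell cycle list and the histones). The blocked naive call was also lost without replicate 2 of control, sh or sd, and the blocked mitochondrial call without sh replicate 2. Without control replicate 2 the blocked mitochondrial median was 0.738 (adjusted p = 3.95e-04), and the blocked cell cycle and histone calls were lost (adjusted p = 0.34 for the former, histone median 0.401). Among protein-coding genes with the block, the naive and mitochondrial lists were not called. Without a block, both were called when no filter was used (adjusted p = 5.3e-05 and 0.00132). The naive median without control replicate 1 and without a block was 0.462. The unblocked fits without 1 library in this comparison set unequal replicate numbers against each other, so the split enters them.

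Cdt1, a replication licensing factor, had 20.2 FPKM in control (SD 7.67, n = 2) and 38.1 in dd (SD 6.997, n = 2). Bub1, a mitotic checkpoint kinase, had 13.3 FPKM in control (SD 6.18, n = 2) and 27.9 in dd (SD 16.9, n = 2). Cobl, of the naive list, had 6.35 FPKM in control (SD 0.663, n = 2) and 11.4 in dd. Zfp42 (Rex1) had 212 FPKM in control (SD 114, n = 2) and 317 in dd (SD 62.3, n = 2), and shares 13.8% of its sampled stretches. Of the mitochondrial transcripts, mt-Co2 had 9050 FPKM in control (SD 5186, n = 2) and 17080 in dd (SD 11340, n = 2). All of its sampled stretches (100%) occur in another gene's transcripts, as do 100% for mt-Nd4l and 98.5% for mt-Atp6, so their values depend on how reads were assigned among copies. Among the genes named by rule, Eif5a2 (chromosome 3, 28781276 to 28798846) had 1.63 FPKM in control (SD 0.238, n = 2) and 6.83 in dd (SD 1.58, n = 2). Zmym2, a zinc finger gene on chromosome 14, had 2.84 FPKM in control (SD 1.24, n = 2) and 11.5 in dd (SD 2.87, n = 2). Chac2 had 11.2 FPKM in dd (SD 1.55, n = 2), Magea4 34 and 43 reads (ratio to control 19.6, exact 95% interval 3.42 to 785) and Mir3473b 4 and 5 reads. The serine protease gene Prss8 had 4.22 FPKM in control (SD 1.33, n = 2) and 0.532 in dd (SD 0.0346, n = 2). Ctf1, which encodes cardiotrophin 1, had 3.72 FPKM in control (SD 1.52, n = 2) and 0.431 in dd (SD 0.0385, n = 2). Ifi27l2a had 0 and 3 reads in dd (0 and 0.318 FPKM). Npy had 11 and 7 reads in control and 0 and 2 in dd (ratio of control to dd 35.3, interval 8.46 to 314). Mir1983 had 8 and 3 reads in control and 0 and 2 in dd (ratio 21.6, interval 4.71 to 200). For Npy and Mir1983 all dd reads came from dd replicate 2, so both ratios depend on that library.

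No gene was called by limma between dd and control. There were 83 genes at an unadjusted p under 0.05, and 1310 with the block, which called 0. By chance 728 would be expected, and 727 with voom, for genes that vary independently. The voom weights called 0 genes without the block (23 unadjusted) and 5 lower genes with it (1344 unadjusted): Rn7s6, Gm23153, Mir6236, Gm42427 and Gm48274, chosen here after their values were seen. Each had its highest value in control replicate 2, as in Rn7s6, a 7S RNA gene with 5062 FPKM there and 0 to 123 FPKM in the other 7 libraries.

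**Figure D4:**
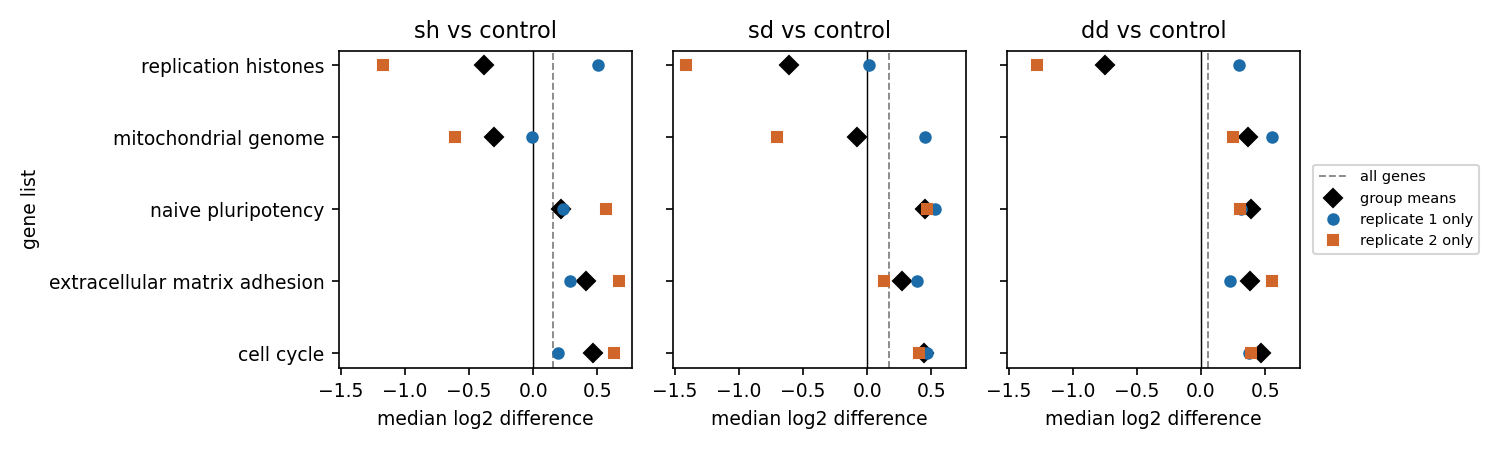
Median log2(FPKM + 1) difference from control for 5 gene lists in sh, sd and dd. Diamonds use group means, circles replicate 1 alone and squares replicate 2 alone, and the dashed line is the median of all genes; the histone medians lie at 0.02 to 0.50 within replicate 1 and at -1.41 to -1.17 within replicate 2.

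The other lists were not called against control, and their medians in sh, sd and dd follow in that order. General pluripotency genes had 0.23, 0.37 and 0.32, the formative and primed list 0.12, 0.12 and -0.07, and LIF and Stat3 targets 0.21, 0.19 and 0.00. The naive list had 0.21 in sh, with 19 of 23 members positive. Of the lists of other cell types, neuroectoderm had 0.22, 0.09 and -0.15, primitive endoderm 0.21, -0.11 and -0.09, trophoblast 0.13, -0.30 and -0.40, and fibroblast feeder genes 0.03, 0.05 and -0.13. The list of the 2-cell-like state had 0.13, 0.54 and 0.36. These low lists were measured beside a mean of 0.337 FPKM for olfactory receptor genes in control replicate 2, 0.256 in sh replicate 2, 0.204 in sd replicate 2 and 0.0251 in dd replicate 2. Signalling lists gave -0.25, -0.24 and -0.30 for Wnt targets, 0.14, -0.16 and -0.16 for FGF and ERK feedback, and 0.26, 0.19 and 0.15 for Nodal and BMP targets. Stress lists gave 0.24, 0.19 and -0.05 for p53 targets, 0.15, 0.22 and -0.13 for Atf4 targets, 0.33, 0.32 and 0.21 for chaperones of the endoplasmic reticulum, 0.20, 0.14 and 0.11 for apoptosis signalling, and 0.15, -0.01 and 0.21 for the interferon response. Metabolic lists gave 0.24, 0.30 and 0.21 for glycolysis and hypoxia and 0.30, 0.29 and 0.20 for cholesterol synthesis. Germline genes had 0.07, 0.22 and 0.17, imprinted genes 0.09, 0.15 and 0.21, chromatin repressors 0.27, 0.37 and 0.28, and cytosolic ribosomal proteins 0.03, 0.04 and 0.15. Camera compares a list with the other genes, and it pointed down at a positive median for several of these lists. In sh these were the general pluripotency, formative and primed, primitive endoderm, trophoblast, fibroblast feeder, FGF and ERK, Nodal and BMP, Atf4, germline, imprinted and ribosomal lists. In sd they were the formative and primed, neuroectoderm, fibroblast feeder, Nodal and BMP, imprinted and ribosomal lists, and in dd the interferon and the LIF and Stat3 lists. The test pointed up at a negative median for the interferon list in sd and the fibroblast feeder list in dd. The mean and the median differed in sign for fibroblast feeder genes in sh, for the neuroectoderm, interferon and ribosomal lists in sd, and for the fibroblast feeder, interferon, LIF and Stat3, and chaperone lists in dd. The matrix list had 0.28 in sd and 0.38 in dd, and the mitochondrial genome -0.07 in sd. The mesoderm and streak list had 4 members above the filter and the Hox list 3, so neither was tested. In no list was a member called over all genes or adjusted over the list alone in the fit without a block. With the block, adjusted over the list alone, 1 member was called in sh (Pou5f1, general pluripotency), 1 in sd (2-cell-like) and 1 in dd (mitochondrial genome).

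The treated groups were also compared with each other. Mitochondrial transcripts were higher in dd than in sh, with all 15 members positive and a median of 0.71 log2 (camera adjusted p = 4.41e-04; 0.916 with an estimated correlation). Their medians within the numbers were 0.56 and 0.74, and with the block the adjusted p was 7.32e-12 (0.981 with the block and an estimated correlation). In the fit without a block, the call was lost without sh replicate 2 (median 0.29), without dd replicate 1 (median 0.47) and with quantile normalization (median 0.32, adjusted p = 0.769). They were also higher in dd than in sd, with all 15 positive and a median of 0.48 (camera adjusted p = 6.24e-05; 0.832 with an estimated correlation). There the median was 0.10 within replicate 1 and 0.86 within replicate 2, and without sd replicate 2 it turned to -0.26 and without dd replicate 1 it was 0.13. With the block, the call against sd was lost with an estimated correlation (adjusted p = 0.996) and without sd replicate 2 (adjusted p = 0.237). Cytosolic ribosomal proteins, of which Rpl24 shares 81.5% and Rpl5 48.5% of its stretches with other genes, were higher in dd than in sd at a median of 0.18 with 30 of 40 members positive; the list was called with the block (adjusted p = 1.21e-04) and not without it (adjusted p = 0.0806). With an estimated correlation the adjusted p was 0.975, and 0.996 with the block as well. Without a block it was also called with median ratio scaling (median 0.28, adjusted p = 0.03) and without a filter on low values (adjusted p = 1.64e-06). Without a block its median was 1.21 without sd replicate 2 (adjusted p = 1.79e-05) and 1.16 without dd replicate 1 (adjusted p = 1.38e-08). It turned to -0.90 without sd replicate 1 and to -0.93 without dd replicate 2. Such unblocked fits set unequal replicate numbers against each other, so the split between the numbers enters them. With the block and without dd replicate 2 the median was 0.286. With the block, the call was lost without sd replicate 2. Trophoblast genes were lower in sd than in sh, with 10 of 11 members negative and a median of -0.31, and the 2-cell-like list was higher, with 8 of 12 positive and a median of 0.25. Its members Zscan4b, Zscan4c, Zscan4e, Zscan4f and Gm5662 share 90.1% to 97.8% of their sampled stretches with other genes and Duxf3 72%, so they may not be independent measurements. The trophoblast and 2-cell-like lists each had a camera adjusted p of 0.0476, and 0.0842 with the block; with an estimated correlation the adjusted p was 0.973 and 0.906. Both calls were also lost with each scaling, without a filter (adjusted p = 0.774 and 0.192), in a fit of only the groups compared (adjusted p = 0.0537 for each), and without control replicate 2, sh replicate 2, sd replicate 1 or sd replicate 2. The trophoblast call was lost without sh replicate 1 as well (adjusted p = 0.436), where the 2-cell-like median was -0.00375 and its call held. The 2-cell-like call was lost with a pseudocount of 0.1 (adjusted p = 0.0707) and with voom (adjusted p = 0.0693). The trophoblast median was 0.14 without sh replicate 2 and 0.07 without sd replicate 1.

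The rule also named genes in these comparisons. Apela, which encodes a peptide hormone of early embryos, had 60.9 FPKM in sh (SD 14.7, n = 2) and 328 in sd, with 94.0 and 563 FPKM in the sd libraries. It overlaps Gm45886 on the same strand and shares 27.4% of its sampled stretches. Mir6400 was at least 2.83-fold higher in sd than in sh and at least 4.04-fold higher than in dd, against a floor of 3 reads per library. Pga5 had 1.96 FPKM in sh and 6.51 in sd, and Stx3 8.42 and 18.4. Catsperz had 0.762 FPKM in sd, and Acp2 2.67 in sh and 0.560 in sd. The mitochondrial tRNA genes mt-Tv and mt-Tt had 77.9 and 76.1 FPKM in sh and 15.8 and 16.8 in sd. Mir466i had 32 and 2 reads in sh and 0 in sd; sh replicate 2 lay below the level of 3 reads in sd, so no fold is given. It shares 30% of its stretches. Between sh and dd, Fbln1, a matrix glycoprotein gene, had 19.4 FPKM in sh (SD 0.270, n = 2) and 7.77 in dd (SD 1.81, n = 2). Snapc5 had 10.9 and 30.6 FPKM, Tmem47 2.65 and 6.92, Eif5a2 2.78 and 6.83, Creb3l1 1.94 and 0.172, and Tstd1 (15.1% of stretches shared) 5.23 and 0.539 in sh and dd. Sox2 was among these genes, at 98.4 FPKM in sh (SD 111, n = 2). Between sd and dd, Chsy1, a chondroitin synthase gene, had 2.30 FPKM in sd (SD 0.0195, n = 2) and 5.71 in dd (SD 0.481, n = 2). Nab1 had 1.36 and 4.37 FPKM, Sult6b1 4.82 and 11.4, Avl9 1.77 and 4.39, Prss8 3.52 and 0.532, Zdhhc5 4.59 and 1.47, Ctf1 2.59 and 0.431, and the antisense gene Pla2g10os (29% shared) 2.27 and 0.389 in sd and dd. Snord8 had 59 and 1 reads in dd and 0 in sd, with dd replicate 2 below the level of 3 reads in sd, and no fold is given either.

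No gene was called by limma in these 3 comparisons, with or without the block. Unadjusted p under 0.05 was reached by 13 genes for sd against sh, 14 for dd against sh and 8 for dd against sd, and by 330, 620 and 147 with the block. By chance 728 would be expected in each, and 727 with voom, for genes that vary independently. The voom weights without the block called 0 genes in each (3, 10 and 4 unadjusted). With the block they called 0 for sd against sh (447 unadjusted), 6 lower genes for dd against sh (1449 unadjusted) and 0 for dd against sd (519 unadjusted). Those 6 genes, chosen here after their values were seen, were Gm10801, Gm10722, Gm10718, Gm10719, Gm10717 and Gm11168. Gm10801 had 3348, 7106 and 5971 FPKM in replicate 2 of control, sh and sd, 378 in dd replicate 2, and 4.68 to 22.0 in replicate 1 libraries. A limma F test over the 3 contrasts against control called 0 genes (22 at an unadjusted p under 0.05), and 0 with the block (574 unadjusted).

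The 3 contrasts against control were compared with each other across genes. The Pearson correlation of log2 differences was 0.688 between sh and sd, 0.627 between sh and dd and 0.80 between sd and dd. Simulated unchanged groups that share the 2 controls gave 0.499, with the same spread for every library of a gene. The control libraries held the fewest reads (6415150 and 3658356), and noisier controls alone would raise the simulated value. The gap to it therefore cannot be read as a shared change. The covariances were 0.21, 0.215 and 0.321, against 0.116 simulated from the spread of the blocked fit, which leaves differences of 0.0942, 0.0995 and 0.205. Against the larger spread of the fit without a block the simulated covariance was 0.627, and the differences were negative, at -0.417, -0.412 and -0.306. Splitting the controls leaves 1 library per part, so part of any excess may come from the shared controls. When the contrasts took different controls, by using replicate 1 for the one group and replicate 2 for the other, the correlations lay between -0.11 and 0.116. With no calls there was no overlap to count. Within a contrast, the log2 differences of the 2 replicate numbers correlated across genes at -0.07 for sh, 0.10 for sd and 0.07 for dd, and 45.9%, 50.3% and 46.2% of genes had the same sign.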

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

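A set of 4 list differences between treated groups was large enough to pass a test of the difference itself, and 3 patterns were then weighed. The tests of the 3 explanations for the histone pattern and of a general fall of pluripotency genes were chosen after their results had been seen, and the last was changed from the list median to its quartiles after the median was seen. Mitochondrial transcripts differed between dd and sh by a median of 0.708 log2 and between dd and sd by 0.483. Trophoblast genes differed between sd and sh by -0.31 and the 2-cell-like list by 0.247. Each passed camera with a preset correlation (adjusted p = 4.41e-04, 6.24e-05, 0.0476 and 0.0476 in that order), and with an estimated correlation none did (adjusted p = 0.832 to 0.973). With the block, the trophoblast and 2-cell-like lists did not pass (camera adjusted p = 0.0842 for each). In fits without a block, the mitochondrial call between dd and sh was lost without sh replicate 2 or dd replicate 1 (medians 0.291 and 0.469), and that between dd and sd without sd replicate 2 or dd replicate 1 (medians -0.263 and 0.125). The other 2 were lost without sh replicate 2 (medians 0.139 and 0.506).

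Replicate 1 and replicate 2 libraries differed in every group, with Actb at 15910 and 76.6 FPKM in the 2 control libraries. Background reads over silent genes were checked on 1600 genes with a mean of at least 50 FPKM. There the highest correlation between different numbers was 0.425, below the lowest of 0.823 within a number. Near-identical copies were checked on 1474 genes with no shared 31-base stretch and a mean of at least 10 FPKM. These gave at most 0.278 between numbers and at least 0.724 within. Neither check can decide, since a mean over both numbers can select genes high in only 1 of them. Such a selection by itself lowers the correlation between numbers. After a trend on transcript length and GC content was removed, the highest correlation between numbers was 0.784 and the lowest within was 0.888. A difference in library preparation or in the cells themselves stays open, as the labels name no batch, and no biological explanation was tested.

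Genes of the replication histone list had negative medians against control in sh, sd and dd, called by camera with a preset correlation and not with an estimated one (adjusted p = 0.973, 0.901 and 0.936). The difference may rest on control replicate 2, since the lowest of the 3 medians within replicate 1 was 0.0182 and those within replicate 2 were -1.17 to -1.41. More RNA without a poly(A) tail in that library is a candidate explanation that these values cannot decide. Within replicate 2, 132 small nucleolar RNA genes had medians of -2.47 to -3.09, but they had passed a filter to which that library contributed. All small nucleolar RNA genes held 0.0829% of its reads and 0.00546% to 0.012% in the treated replicate 2 libraries. In replicate 1 libraries they held 0.0386% to 0.111%, so their share in control replicate 2 was not above that of every replicate 1 library. Mitochondrial tRNA genes likewise held 0.0807% there and 0.101% in sh replicate 1. Other classes were highest in control replicate 2. Small nuclear RNA genes held 0.0543% there and 0.000406% to 0.00505% elsewhere. Genes annotated as miscellaneous RNA held 0.385% there and 0.000201% to 0.00865% elsewhere. The histone median in control replicate 2 was 32.1 times the olfactory receptor mean. This cannot decide on background reads, because the histone genes had passed a filter to which that library contributed and the receptors were unfiltered. Keratin-associated genes, also unfiltered, had a mean of 1.13 FPKM there. An effect of the treatments stays open as well.

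Pou5f1 was lower in each of the 6 treated libraries than in the control library of its number. Reads moved to near-identical copies are argued against, since the sum over Pou5f1 and its copy Gm5712 had log2 ratios to control of -0.827 or lower. A scaling difference is argued against by quantile normalization, after which the differences were -0.718 or lower. The naive list did not fall as a set in these values: its lowest lower quartile over the 3 contrasts was 0.0845 while Pou5f1 lay at -2.87 to -1.55. That check was chosen and changed after the values were seen, so it cannot decide on a fall of pluripotency genes as a whole. The general pluripotency list, which holds Pou5f1 and Sox2, had medians of 0.23, 0.366 and 0.324 in sh, sd and dd. Sox2 in sh lay at -1.995. An effect of the treatments on Pou5f1 stays a hypothesis, found and tested on the same 8 libraries, and the split between replicate numbers was not excluded as a contributor.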

How the results depend on the processing

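The counts of 0 called genes in the 6 contrasts held under every alternative set for them before the data were examined, and that of the F test under those set for it, which left out the fit of only the groups compared and a minimum size of change. Most of these fits had no block. On simulated data for sh against control such a fit recovered 0% of genes changed 16-fold, so the counts had little room to move. Of alternatives added after seeing the data, voom with the replicate block called 5 genes for dd against control and 6 for dd against sh, and 0 elsewhere. Genes named by the rule were called under no alternative, and in 21 of 2164 recomputed values, from 17 of 112 gene and contrast pairs, the sign differed from the one reported.

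The counts of called lists moved with most settings. They were 4, 1 and 2 for sh, sd and dd against control and 2, 1 and 1 for sd against sh, dd against sh and dd against sd. They fell to 0 in all 6 with an estimated correlation, with fry, and with an estimated correlation and the block. With a pseudocount of 0.1 they were 0 for sd, 0 for dd and 2 for dd against sh. Without a filter they were 0, 3, 13, 0, 12 and 4 in the order above. With a mean of at least 5 FPKM they were 3 for sd, 0 for dd, 1 for sd against sh and 3 for dd against sh. Quantile normalization gave 2 for sh, 1 for dd, 0 for sd against sh and 0 for dd against sh, and median ratio scaling gave 0 for sh, sd, dd and sd against sh and 2 for dd against sd. A fit of only the groups compared gave 0 for sd against sh. The replicate block gave 3 for sd, 4 for dd, 0 for sd against sh and 2 for dd against sd. Voom gave 4 for sd, 1 for sd against sh and 2 for dd against sh, and voom with the block gave 4 for sd, 1 for sd against sh and 2 for dd against sd. Protein-coding genes with the block gave 5 for sd and 2 for dd against sd. Leaving out 1 library gave 4 to 9 for sh, 1 to 10 for sd, 2 to 7 for dd, 0 to 9 for sd against sh, 1 to 7 for dd against sh and 1 to 9 for dd against sd. With the block and without 1 replicate 2 library, the ranges were 0 to 4, 0 to 3, 0 to 3, 0 to 2, 1 to 2 and 0 to 2. The cause was not tested.

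Without control replicate 2 the histone medians turned to 1.07, 0.735 and 0.835 in sh, sd and dd, and with the block to 0.525, 0.239 and 0.401, and the cell cycle test in sh turned down at a median of 0.336; without control replicate 1 these were -1.71, -1.82, -1.88 and 0.484. When 1 library was left out without the block, the mitochondrial median ranged from -0.801 (without sh replicate 1) to -0.0341 (without sh replicate 2) in sh, where it was -0.00763 with the block and without control replicate 2. For dd against sd it ranged from -0.263 (without sd replicate 2) to 1.14 (without sd replicate 1). Likewise without the block, the ribosomal median for dd against sd ranged from -0.927 (without dd replicate 2) to 1.21 (without sd replicate 2). Libraries left alone in a group were assumed to vary like the others. Without the block, such fits also set unequal replicate numbers against each other, so the split between the numbers enters these medians.

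Correlations between contrasts moved from 0.688 (sh and sd), 0.627 (sh and dd) and 0.80 (sd and dd) to 0.678, 0.643 and 0.765 with a pseudocount of 0.1 and to 0.673, 0.593 and 0.81 with a mean of at least 5 FPKM. Quantile normalization gave 0.701 for sh and sd and 0.647 for sh and dd. Leaving out 1 library gave 0.305 to 0.926, 0.232 to 0.913 and 0.379 to 0.949. No value was simulated for these reduced designs. With 1 control left, the split between replicate numbers enters both contrasts, so they cannot be set against the simulated 0.499. The replicate block left them unchanged. Deviations of same-numbered libraries from their group means correlated at 0.75 to 0.893 across genes in the 6 pairs of groups; the labels do not say that the numbers pair libraries. Depth limits low genes in control replicate 2 most, at 0.82 FPKM per kilobase for 3 reads.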

Other observations

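The genes and classes in this part were chosen after their values were seen. Gm10800, a predicted gene (chromosome 2, 98666547 to 98667301), had 44.9 to 138 FPKM in replicate 1 libraries, and in replicate 2 it had 18590 in control, 51650 in sh, 45010 in sd and 3021 in dd. Dppa5a, a pluripotency marker gene on chromosome 9, had 292 to 557 FPKM in replicate 1 and 5866 to 8584 FPKM in replicate 2. Processed pseudogenes held 29.2% to 30.9% of the FPKM total in replicate 1 libraries and 56.9% to 64% in replicate 2 libraries. Vomeronasal receptor genes, which like the olfactory receptors belong to sensory tissue, had a value above 0 for 9.48% to 14.1% of 327 genes in replicate 1 and 62.1% to 95.1% in replicate 2. The replicate 2 library with the lowest such share, dd, held the most reads of the 4 at 20386654, and control replicate 2, with 3658356, had 87.8%.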
